A study of Mus musculus with 7 samples.

How the data were processed

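Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on retinas of 8-week-old mice with an antibody against Crx, a homeodomain transcription factor of photoreceptors, or with IgG as the control. Wild-type (wt) mice were C57BL/6. Knockout (ko) mice lacked Nrl, a transcription factor needed to form rods. The strain label is C57BL/6 for all samples, those of the knockout included. The 7 libraries form 4 groups: Crx in wt (2 libraries), IgG in wt (1), Crx in Nrl ko (2) and IgG in Nrl ko (2). Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The read names carry 1 instrument for the wt libraries and another for the Nrl ko libraries, so instrument and genotype cannot be told apart.

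For each library the authors deposited a list of aligned reads of 1 fixed length on the mouse mm9 build, per the submitters' processing notes, with a score between 0 and 1 per read. The meaning of this deposited score is not given in the sources used here, and neither are the aligner and its filters. For each Crx library the authors also deposited a track of clusters with a count of reads at each base. The deposited count equalled the depth recomputed from the same library's reads, duplicates included, with a tolerance of 0 reads, at all bases of the wt tracks and at all but 7 and 8 bases of the Nrl ko tracks. How clusters were called and what was subtracted are not given in the sources used here. Both wt cluster lists hold nearly the same positions, so they were not read as independent calls.

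Reads with the same start and strand were counted as 1, which left 3857618 to 9171396 unique reads per library. Each read was moved 75 bp towards the middle of its fragment. Covered stretches of a track within 100 bp of each other were joined into 1 cluster. Overlapping or touching clusters of the 4 Crx libraries were merged, and a region was kept when both replicates of at least 1 genotype had a cluster in it. This gave 6394 regions with a median width of 284 bp. The rule was not equally strict for the genotypes. It left out 0 regions of a single wt list, since these lists are nearly the same, and 4348 and 1308 regions of a single Nrl ko list. Coordinates are mm9, counted from 1. Levels in RPM are unique reads in a region or window scaled to the unique reads of the library.

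Regions were compared between genotypes with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 5%, on the 4 Crx libraries, after removing regions with few reads (filterByExpr, minimum count 10). The planned main scaling was TMM over the regions, which sets the typical region to no change, so that a call means higher or lower relative to other regions. Another scaling, also set before the data were examined, measures change against the genomic background. It is based on TMM over 10 kb bins outside the merged regions of any Crx library, kept or not. The scalings differed by 1.99 on the log2 scale, and counts of both are given for the comparison of regions between genotypes and for the interaction. Crx by genotype interaction and the IgG comparison were tested in 1 fit of all 7 libraries, with regions scaled as above.

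Windows of 1 kb over the whole genome, scaled by TMM over 10 kb bins, were tested in 1 fit of all 7 libraries, after the same filter on few reads, to which Crx reads also count. They replaced windows around transcription starts, because no mm9 genome or annotation was used here; this change was made after the data were seen. For the same reason the planned gene lists, the location of regions in genes, motifs, the GC correction, the named genes and reads over the Nrl gene body were not analysed here, and no region was matched to a gene.

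Unless stated otherwise, regions and windows named below were chosen by a rule set before the data were examined. The rule takes the 10 largest changes in each direction past the 5% threshold, with at least 30 reads over the libraries compared and no overlap between the groups' libraries. It also takes the 5 tallest regions of each genotype by mean RPM. The rule was carried over to the 1 kb windows, which were brought in after the data were seen. For the interaction all called regions are named, without the conditions on reads and overlap. Where a group had 0 reads, the fold is a lower bound computed with 3 reads over the group. Where it had 1 to 3 reads, the ratio is given with its 95% exact counting interval. Shares of reads carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only.

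The tests were tried on counts simulated at the depths of these libraries, from 1 mean per region or window pooled over the libraries used and 1 fixed dispersion. Regions were simulated for the Crx libraries. Windows were simulated for the Nrl ko libraries alone, scaled to total reads, with 3654 tested. At regions, log2 changes of -2, -1, 1 and 2 were recovered in 44%, 12%, 34% and 100% of 50 simulated regions each, with 3 false calls among 98. At windows the shares were 14%, 4%, 20% and 98%, with 0 false calls among 68. In this setting decreases were recovered less often than increases of the same size. Other depths were not simulated, and neither was a common difference between genotypes such as these data have. The recovered shares and false calls thus do not carry over to the fits below.

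After duplicate removal the wt Crx libraries differed at regions by less than sampling noise, with a chi-square per degree of freedom of 0.847, against 1.41 for the Nrl ko pair. With all reads the wt value was 1.06, above sampling noise by 3.15 SD, and over 10 kb bins it was 1.08, above by 23.3 SD. They shared 0.603% of read positions, 1.32 times the share after a 20 bp shift, and this ratio was 1.27 to 1.48 for other pairs. They were kept as 2 libraries, and a fit with both summed into 1 is given among the alternatives.

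Alternatives covered duplicate reads, scaling, low-count filters, DESeq2 1.42.0, region sets and widths, read position, depth, window size, the replicate number as a block and, in the tests of Crx regions and windows, replicated libraries left out in turn. The IgG wt library was never left out. Added after the data were seen were a minimum score of 0.9, merging only touching stretches, leaving out chromosome 14, scaling over regions of both Nrl ko lists, summing the wt libraries, leaving out replicated libraries in turn in the interaction and IgG tests, and thinning the IgG wt library at random to its reads with a score of at least 0.9. A low-score read is one with a score under 0.98. This limit, the excess of 5 points per 1 Mb bin, the minimum of 15 wt reads for a read-free stretch, the 5 bp reach between reads and the 10 kb reach between regions were chosen after the data were seen. Summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.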

Results

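Crx occupancy was measured by ChIP-seq in adult retina of wt and Nrl ko mice, with IgG libraries as the background. The Crx libraries of wt held 4292867 and 4301698 reads, and those of Nrl ko held 12500527 and 10464363. The IgG libraries held 6047142 reads in wt and 12138346 and 10989616 in Nrl ko. Duplicates made up 10.1% and 9.34% of the Crx wt reads and 30.1% and 19.3% of the Crx Nrl ko reads. They made up 10.9% of the IgG wt reads and 24.4% and 30.2% of the IgG Nrl ko reads. In the IgG wt library 38.4% of reads had a score under 0.9, against 0.210% to 1.52% in the other libraries.

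The genotype labels were checked first. On chromosome 14, which carries Nrl, a stretch of 5499 bp from 56137177 to 56142675 held reads in every wt library and in no Nrl ko library. The Crx wt libraries had 72 and 77 unique reads there and the IgG wt library had 27. The 4 Nrl ko libraries had 0, where 170.5 would be found at the IgG wt rate, and a count of 0 allows up to 1.76% of that number. Among single stretches without Nrl ko reads the next held 66 wt reads. On chromosome 7 between 27661323 and 27748557, though, 4 longer stretches of 9419 to 21622 bp, some parted by a single base, held 42, 49, 49 and 49 wt reads, so such a loss was not found on chromosome 14 alone. In the other direction, stretches without wt reads held up to 229 Nrl ko reads. The stretch was chosen after its values were seen and was not matched to a gene, so it is not a direct reading of the targeted gene.

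**Figure D1:**
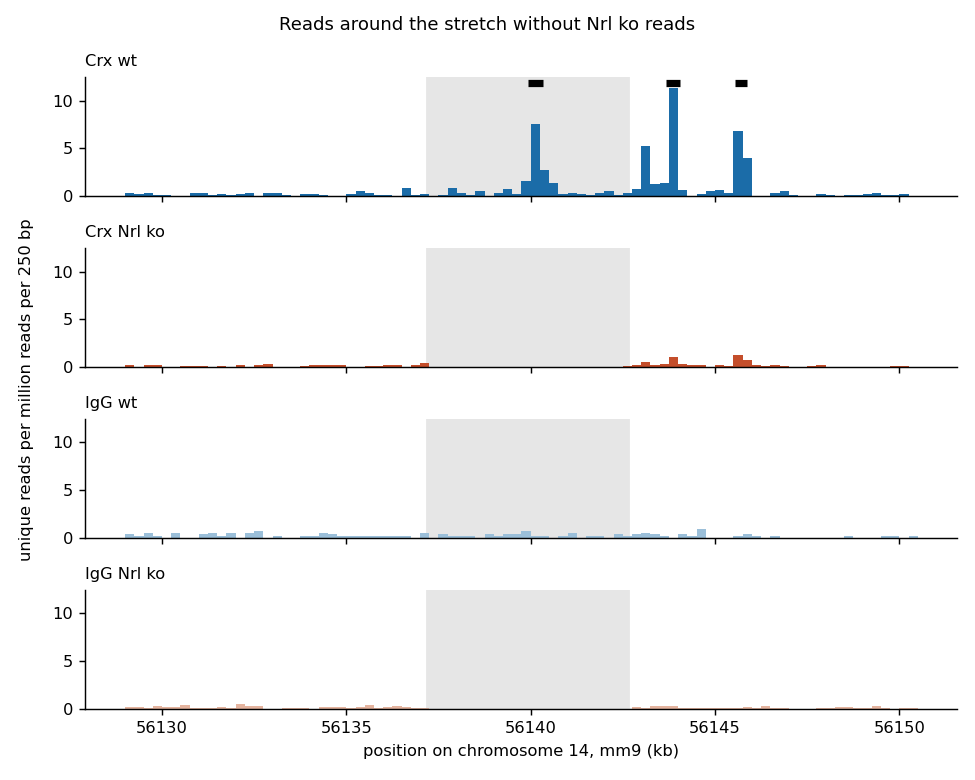
Unique reads (RPM) in 250 bp steps along chromosome 14 (mm9, kb) in the Crx and IgG libraries of each genotype, with the stretch from 56137177 to 56142675 shaded and called regions as black bars. All 4 Nrl ko libraries have 0 reads in the shaded part.

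The stretch holds a Crx region at 56139940 to 56140337, with 45 and 37 reads in the Crx wt libraries and 0 and 0 in the Crx Nrl ko libraries. Beside it, the region at 56143678 to 56144041 fell from 12.9 ± 1.19 RPM in wt to 1.28 ± 0.299 RPM in Nrl ko (SD, n = 2 each). This was a log2 change of -1.41 relative to other regions (edgeR adjusted p = 0.000657). The region at 56145545 to 56145874 had 10.9 ± 1.19 and 1.69 ± 0.207 RPM, a log2 difference of -0.78 that did not pass the test (adjusted p = 0.0632), though it passed under some alternatives.

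The deposited clusters show where Crx signal was found in each library. The Crx wt lists held 5560 and 5546 clusters, and the Nrl ko lists held 7818 and 3923. Of the clusters of wt replicate 1, 46.7% met a cluster of Nrl ko replicate 1 and 31.6% met one of Nrl ko replicate 2. The Nrl ko lists met each other at 29.0% of the clusters of replicate 1 and 57.9% of those of replicate 2. Of 6394 regions, 1438 were in all 4 lists, 2621 were in the wt lists and neither Nrl ko list, and 854 were in both Nrl ko lists and not in the wt lists. Another 1481 were in the wt lists and 1 Nrl ko list. These are counts without a test, and they move with how much was called in each library. They also carry the unequal rule for regions, which dropped regions of a single Nrl ko list but had no such effect on the wt lists.

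A larger share of Crx reads lay in these regions in wt than in Nrl ko. It was 3.17% (95% interval 3.15% to 3.19%) and 3.61% (3.60% to 3.63%) in the wt libraries. It was 1.04% (1.03% to 1.05%) and 1.08% (1.07% to 1.08%) in the Nrl ko libraries. IgG put 0.138% of wt reads and 0.169% and 0.341% of Nrl ko reads in the same regions. No test was run on these shares. The set of regions leans towards wt, with 5540 in both wt lists and 2292 in both Nrl ko lists, so the shares are not independent of how it was formed.

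**Figure D2:**
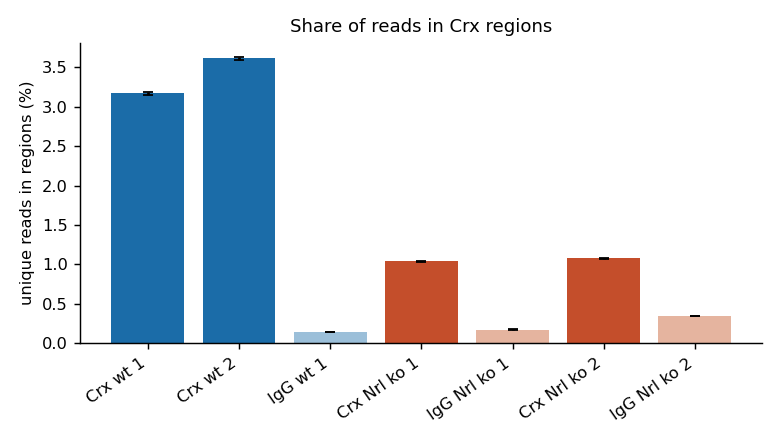
Percent of unique reads in the 6394 regions for each library, with bars from 0 and error bars of the 95% exact interval, which covers counting error only. The Crx wt libraries stand at 3.17% and 3.61% and the Crx Nrl ko libraries at 1.04% and 1.08%.

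Regions of the wt lists had more Crx signal in wt than in Nrl ko. Regions in the wt lists alone had 17.7 ± 1.75 RPM per kb in wt and 2.94 ± 0.191 in Nrl ko (SD, n = 2 each), over an IgG level of 1.32 ± 0.614 in Nrl ko. Regions in all 4 lists had 22.6 ± 2.01 and 8.10 ± 0.673 RPM per kb. Regions in both Nrl ko lists alone went the other way, with 4.66 ± 0.302 RPM per kb in wt and 7.64 ± 1.03 in Nrl ko. The lists were made from the same reads, so these levels are not independent of how the classes were formed.

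**Figure D3:**
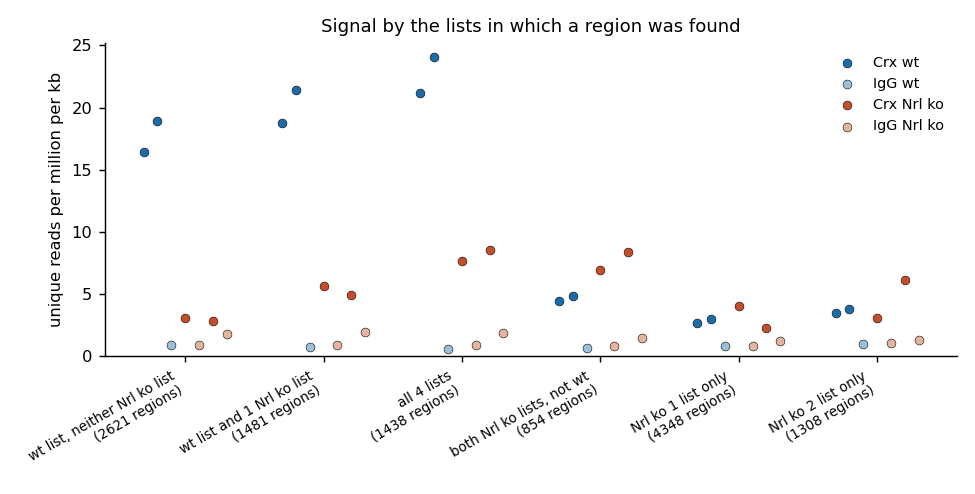
Unique reads (RPM per kb) in each library (points) for regions grouped by the cluster lists that hold them. Crx signal in wt lies above that in Nrl ko in the wt classes, such as 17.7 against 2.94 on average in regions of the wt lists alone, and below it in regions of both Nrl ko lists.

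The main comparison asks how Crx occupancy differs in retina without Nrl. Against the genomic background, Crx signal was lower in Nrl ko at 5140 of 5923 tested regions and higher at 209, with a median log2 change of -2.05. Relative to other regions, 1044 were higher and 644 were lower in Nrl ko. The share of higher regions among calls was thus 61.8% under the relative scaling and 3.91% under the background scaling (edgeR, 5% adjusted). The 644 lower regions and 209 of the higher regions were called in the same direction under both. For the lower ones this was close to given, since the background scaling lowers log2 changes by a median of 1.99. Of the other regions called higher relative to the rest, 271 were lower against background and 564 were not called. The median log2 change was 1.72 among the higher and -1.63 among the lower, and the same with groups at 0 reads set to their bound.

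The direction of change was counted in each class of regions. The classes come from clusters of the same reads, so the direction is largely set by how they were formed. Relative to other regions, 539 of 562 tested regions in both Nrl ko lists alone rose and 0 fell, and 208 also rose against background. Of 2448 tested regions in the wt lists alone, 548 fell and 16 rose. Of 1438 regions in all 4 lists, 419 rose and 21 fell relative to other regions, but 0 rose and 1265 fell against background. DESeq2 called 632 higher and 101 lower under the relative scaling, and without Nrl ko replicate 2 the counts were 579 and 315. Each genotype was sequenced on its own instrument, so no within-instrument value can be had.

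**Figure D4:**
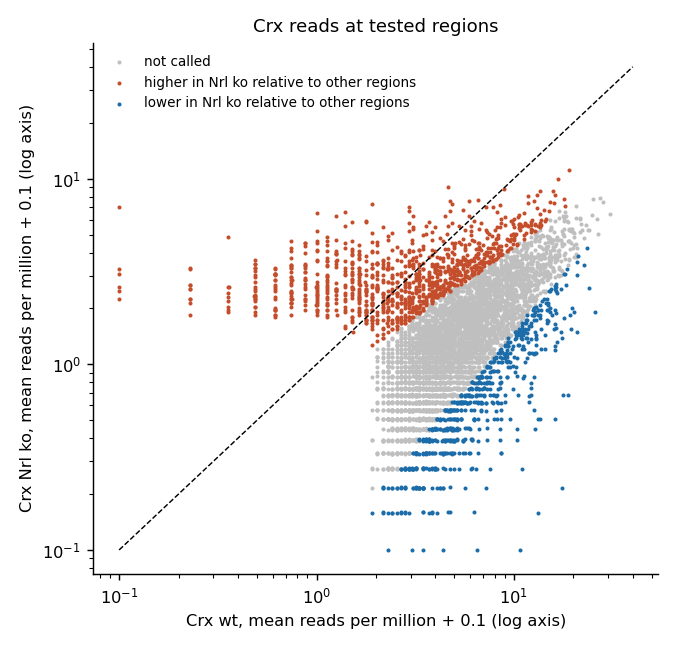
Mean RPM in the Crx libraries of wt (x axis) and Nrl ko (y axis) at the 5923 tested regions, both on log axes with the small offset given in the axis labels; the dashed line marks equal values. Of the regions called relative to the others, 1044 are higher (red) and 644 lower (blue) in Nrl ko, and most regions lie below the dashed line.

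The named regions higher in Nrl ko had almost no Crx wt reads, and each also passed the test against background. The region on chromosome 6 at 60691695 to 60692162 had 57 and 62 Crx reads in the Nrl ko libraries and 0 and 0 in wt, at least 67.5-fold higher relative to other regions. The 1 kb window that starts at 60691001 holds most of it and was at least 17.2-fold higher against background. Regions on chromosome 14 at 18822900, chromosome 10 at 68573290, chromosome 16 at 74166899, chromosome 14 at 116178545 and chromosome 3 at 144224298 also had 0 Crx wt reads. They were at least 30.6-fold, 28.9-fold, 24.4-fold, 23.3-fold and 21.0-fold higher relative to other regions. On chromosome 1, the region at 83394117 had 81 Nrl ko reads and 2 wt reads, a ratio of Nrl ko to wt relative to other regions of 69.0 (18.5 to 579). The region at 82062830 had 54 and 1, a ratio of 91.9 (15.8 to 3698). Regions on chromosome 4 at 19207750 and chromosome 13 at 57551705 had ratios of 93.6 (16.1 to 3765) and 74.9 (12.8 to 3025). The highest adjusted p of these 10 was 7.12e-11 (edgeR), and every Nrl ko library lay above every wt library, as the naming rule required.

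The named regions lower in Nrl ko had almost no Crx reads there. Each also passed the test against background, which adds little, since that scaling lowers log2 changes by a median of 1.99. The region at 56139940 on chromosome 14, in the read-free stretch, was at least 16.1-fold lower relative to other regions. Regions on chromosome 7 at 53078704, with 20 and 30 wt reads, and chromosome 4 at 3865764, with 15 and 18, had 0 Nrl ko reads and were at least 9.79-fold and 6.46-fold lower. On chromosome 9, the region at 107581885 had 13.1 ± 2.82 RPM in wt and 0.0572 ± 0.0810 in Nrl ko, a ratio of wt to Nrl ko relative to other regions of 59.9 (10.5 to 2389). The region at 59798837 had 17.5 ± 3.51 and 0.116 ± 0.00276 RPM, a ratio of 39.9 (10.8 to 333). On chromosome 6, the region at 115881613 had 10.9 ± 3.38 and 0.174 ± 0.0782 RPM, a ratio of 16.6 (5.50 to 82.3). Regions on chromosome 5 at 108817232, chromosome 3 at 94778437, chromosome 2 at 29475102 and chromosome 17 at 83750188 had 1 Nrl ko read each, with ratios of 28.2, 21.1, 20.6 and 18.2. Their intervals were 4.82 to 1136, 3.56 to 858, 3.46 to 835 and 3.03 to 742. The highest adjusted p of the 10 was 7.49e-05 (edgeR).

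The tallest regions of wt had lower Crx levels in Nrl ko against background and were not called relative to other regions. The tallest, on chromosome 3 at 30647196 to 30647693, had 30.4 ± 3.05 RPM in wt and 6.35 ± 0.727 in Nrl ko. Its log2 change against background was -2.36 (edgeR adjusted p = 1.27e-08), and its relative difference of -0.34 did not pass (adjusted p = 0.166). The others, on chromosome 3 at 30644861, chromosome 4 at 137886052, chromosome 7 at 106578169 and chromosome 1 at 89699901, fell against background by 2.04, 1.89, 2.51 and 2.23. None of the 5 passed the relative test, with differences between -0.50 and 0.12. This depended on which regions set the scale: with TMM over regions of both Nrl ko lists, added after the data were seen, all 5 were called lower, such as the region on chromosome 3 at 30644861 (log2 change -0.986, adjusted p = 8.77e-05).

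The tallest regions of Nrl ko rose relative to other regions, but only 1 of the 5 rose against background. On chromosome 18, the region at 74185176 to 74185923 had 4.51 ± 0.512 RPM in wt and 8.93 ± 2.43 in Nrl ko. Its log2 change was 2.89 ± 0.26 (SE) relative to other regions and 0.88 ± 0.31 against background (edgeR adjusted p = 0.0104). Regions on chromosome 6 at 29344226, chromosome 10 at 93761175 and chromosome 2 at 144345387 rose by 1.12, 1.16 and 1.02 relative to other regions and fell against background by 0.88, 0.85 and 0.99. The region on chromosome 2 at 93431902 rose by 1.89 relative to other regions, and its log2 difference of -0.11 against background did not pass the test. With TMM over regions of both Nrl ko lists the regions at 29344226, 93761175 and 144345387 were no longer called (log2 differences 0.179, 0.214 and 0.055).

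Crx enrichment over IgG was tested in windows of 1 kb over the whole genome that had enough reads over all libraries, Crx reads included. In wt, Crx was above IgG at 7300 of 146378 windows, with a median log2 change of 3.66. Of these, 74.5% overlapped one of the 12050 merged regions of any Crx library, a wider set than the 6394 kept regions. The window on chromosome 11 at 63705001 had 22.2 ± 1.27 RPM of Crx and 0 IgG reads, at least 41.6-fold higher. Windows on chromosome 16 at 96339001, chromosome 12 at 29502001 and chromosome 15 at 100946001 were at least 36.3-fold, 35.6-fold and 32.4-fold higher. Crx was below IgG at 337 windows, and the 10 named ones all lay on chromosome X. The window on X at 72894001 had 59 IgG reads and 0 Crx reads, at least 27.1-fold lower, and that at 80642001 had 62 and 2, a ratio of IgG to Crx of 42.7 (11.3 to 360). With reads of a score of at least 0.9 alone, 77 windows were lower. Without wt Crx replicate 1 or 2, 3418 and 2660 windows were higher and 53 and 49 lower. IgG in wt is 1 library, whose spread was assumed to be that of the other groups.

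In Nrl ko, Crx was above IgG at 1484 windows, with a median log2 change of 2.22. Of these, 97.6% overlapped one of the same 12050 regions of any Crx library. That set includes regions of a single Nrl ko list, called from the same reads. The window on chromosome 19 at 47775001 had 4.19 ± 0.264 RPM of Crx and 0.174 ± 0.0620 of IgG, a ratio of Crx to IgG of 23.5 (7.74 to 117). On chromosome 1, the window at 128052001 had 4.73 ± 1.51 and 0.229 ± 0.139 RPM, a log2 change of 4.22 (edgeR adjusted p = 2.85e-07). Windows on chromosome 5 at 9118001 and chromosome 2 at 93626001 had ratios of 36.3 (6.12 to 1471) and 28.9 (7.66 to 244). Crx was below IgG at 12 windows, and 3 met the naming rule, on chromosome 14 at 122506001, chromosome 7 at 147311001 and chromosome 4 at 155079001, with log2 changes of -2.77, -2.67 and -2.37. Of the 1484 windows, 1099 were also enriched in wt, against 74.0 for independent lists. That expectation treats all tested windows as alike. Both lists also come from 1 fit and 1 filter to which Crx reads count, so the excess over it says little. Without IgG Nrl ko replicate 2, 2963 windows were enriched, and without Crx Nrl ko replicate 2, 277. The count of windows below IgG also moved with DESeq2 and with single libraries left out, as given in the section on processing.

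Between genotypes, Crx signal was lower in Nrl ko at 7422 windows and higher at 188, scaled on background. Of the lower windows 56.8% overlapped one of the 12050 merged regions of any Crx library, and of the higher ones 60.1%. The rest lay where no Crx library had a cluster, so these counts are not counts of Crx sites. The window on chromosome 14 at 56140001, in the read-free stretch, had 98 wt reads and 0 Nrl ko reads, at least 76.7-fold lower. On chromosome 9 the window at 120842001 had 7.60 ± 1.58 RPM in wt and 0.114 ± 0.162 in Nrl ko, a ratio of wt to Nrl ko of 69.3 (18.3 to 585). There the IgG Nrl ko libraries had 9 and 8 reads, against 2 and 0 of Crx. Crx in Nrl ko thus lay below its own control, and the ratio is not a fall to the control level alone. On chromosome 6 the window at 115881001 fell by 5.11 on the log2 scale (edgeR adjusted p = 7.86e-17). It had 3 and 4 IgG Nrl ko reads, against 5 and 1 of Crx. Among higher windows, those on chromosome 14 at 116178001, chromosome 18 at 81645001 and chromosome 6 at 60782001 had 0 Crx wt reads. They were at least 7.67-fold, 5.54-fold and 5.11-fold higher. The IgG Nrl ko libraries had 2 and 4 reads at the first, against 23 and 31 of Crx. They had 10 and 9 at the second, against 19 and 20, and 8 and 3 at the third, against 14 and 22. Much of the signal at the last 2 was thus in the control too. The window on chromosome 1 at 24620001 had 10 and 57 Crx reads in the Nrl ko libraries, so its call rested mainly on replicate 2. There IgG Nrl ko replicate 2 had 46 reads. DESeq2 called 18 windows higher and 3615 lower, and leaving out single Crx libraries gave 3 to 60 higher and 905 to 3689 lower.

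The Crx change between genotypes was also set against the IgG change at the same regions. The interaction was called at 10 regions, 9 higher and 1 lower (edgeR; 190 and 462 at an unadjusted p under 0.05; DESeq2 called 22 and 0) under the relative scaling. Under the background scaling 8 were higher and 1590 lower, so the direction of most calls depends on the scaling, and with the replicate number as a block 0 and 0 were called under the relative scaling. The lower one was the region on chromosome 9 at 59798837, with 58 and 78 Crx reads in wt, 1 and 1 in Nrl ko and 2 IgG wt reads (log2 interaction -5.24, adjusted p = 0.0402), and it lost the call when any 1 of the 6 replicated libraries was left out; without Crx Nrl ko replicate 2 another region was called lower in its place. Among the higher ones, the region on chromosome 14 at 18822900 had 0 Crx reads in wt and 21 and 33 in Nrl ko (adjusted p = 0.0402). The region on chromosome 2 at 112360007 had 69 Crx reads in wt and 48 in Nrl ko, with 10 IgG wt reads against 2 and 1 in the IgG Nrl ko libraries. The others were on chromosome X at 72902589 and 143704252, chromosome 16 at 3234405, chromosome 18 at 44684231, chromosome Y at 2495851 and 2865222, and chromosome 4 at 107663371. Of the IgG wt reads in the 10 regions 57.0% had a score under 0.9, and with a minimum score of 0.9 no region was called in either direction. Thinning the IgG wt library at random to the same 3426316 reads also lost calls, leaving 0 to 6 over 20 draws.

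The IgG comparison between genotypes had little power, since IgG in wt is 1 library with a median of 1 read per region. IgG was called higher in Nrl ko at 0 regions and lower at 5 (edgeR; 377 and 90 at an unadjusted p under 0.05; DESeq2 called 0 and 2). The region on chromosome 6 at 125826954 had 30 IgG reads in wt and 2 and 2 in Nrl ko (log2 change -4.78, edgeR adjusted p = 8.45e-09), and its Crx signal also fell relative to other regions (log2 change -2.42). On chromosome 17 the region at 4626282 had 18 IgG wt reads and 2 and 1 in Nrl ko, and on chromosome 8 that at 84065178 had 17, 1 and 0. The others were on chromosome X at 143704252 and chromosome 6 at 125568039. These regions were named because the count was small, after their values were seen, and with a minimum score of 0.9 the count was 0. The median log2 IgG change from wt to Nrl ko was 0.899 at regions where Crx was not called different, 1.263 where Crx was higher and 0.103 where it was lower, so the few calls do not show that IgG was alike.

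**Figure D5:**
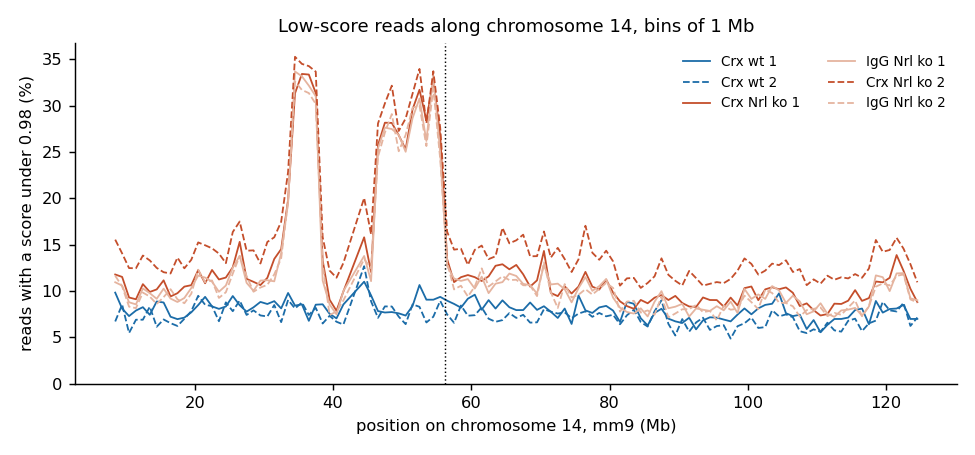
Percent of unique reads with a score under 0.98 in 1 Mb bins along chromosome 14 (mm9, Mb) for the Crx libraries and the IgG Nrl ko libraries, with a dotted line at the start of the read-free stretch. From 33 to 38 Mb and from 46 to 56 Mb the Nrl ko libraries average 30.1% and 28.2% and the Crx wt libraries 8.46% and 8.17%. The IgG wt library is not drawn, since its share was 35.3% to 45.6% in the bins of the chromosome, inside and outside these segments.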

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

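The library depth test, the test of nearby low-score reads, the test of low-score IgG wt reads, that by matched regions and that by thinning of this library were set before their values were seen, though after the patterns and related values such as the shares without thinning; the tests of run quality, repeats, the chromosome of the bins, region choice, a common factor, yield, the folds left with a minimum score and the common part of the change were chosen after.

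A signal in the read scores, which no comparison used, stood apart: in all Nrl ko libraries the share of low-score reads was higher on chromosome 14 from 33 to 38 Mb (mean 30.1%, Crx wt 8.46%) and from 46 to 56 Mb (28.2%, Crx wt 8.17%), and in 1 bin on chromosome 10 from 79 to 80 Mb (19.4%, Crx wt 9.14%), while the IgG wt library, at 41.6% and 39.4% in the chromosome 14 segments and 35.3% to 45.6% along that chromosome, was not used as a reference. Lower run quality and repeats were weighed as explanations. The Nrl ko excess was 3.26 points in other bins of chromosome 14 against 20.6 in the shifted bins. The Crx wt libraries differed between these bins by 0.630 points. Shifted bins were picked for an Nrl ko excess over Crx wt, so the first contrast is largely given by that choice and cannot decide on run quality. The choice also favours bins with a low Crx wt share, so the second value is only weak evidence against repeats. A candidate explanation is a variant of the knockout strain against the reference: in shifted bins a read within 5 bp of a low-score read of another Nrl ko library was low-score 5.86 times as often as one near another read, against 1.67 for Nrl ko and Crx wt. The preset bound of 2 was weak, since the ratio was also 3.52 between Nrl ko libraries in other bins and 3.01 between the wt libraries in the shifted bins. What remains is the wider contrast within and between genotypes, 5.86 against 1.67 in the shifted bins and 3.52 against 2.67 in other bins. Pairs of Nrl ko libraries share 1 instrument and pairs with Crx wt do not, so genotype and instrument cannot be told apart here. The shifted bins were also picked on the same scores, so the contrast does not decide for a variant. That 93.8% of the 16 shifted bins lay on the chromosome of Nrl restates the pattern and decides nothing: with a score limit of 0.95 no bin was shifted, and with a limit of 0.99 or an excess of 3 points 17 and 32 bins on other chromosomes were.

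The lower Crx signal in Nrl ko at most regions was weighed against depth, region choice, yield and precipitation. With all libraries thinned to the smallest the wt share of reads in regions was 3.17 times the Nrl ko share, against 3.21 without thinning. Apart from duplicate removal, random thinning leaves the expected share in fixed regions unchanged, and clusters were not called again. This test thus cannot decide on depth. Region choice is argued against as the whole of it. At tested regions of both Nrl ko lists, in the wt lists or not, the median log2 change against background was -1.20. The 562 of them outside the wt lists had a median of 0.614, though. A single factor for all regions leaves out that 28.5% of regions still differed after scaling over regions, though DESeq2 called fewer (632 higher and 101 lower of 5923) and so did libraries thinned to the smallest (413 and 132 of 4664). At regions lower in Nrl ko, the IgG signal of the Nrl ko libraries was 0.749 and 1.53 times that of wt and the Crx signal 0.0937 times, but the median log2 IgG change was 0.103 there, 0.899 at regions not called and 1.263 at regions higher, so a part from lower yield on the other instrument stays open. The common part of the change, a median of -2.05, cannot be told apart from weaker precipitation or the instrument, because each genotype was sequenced on 1 instrument; a change with genotype stays open as a hypothesis.

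The change from IgG to Crx differed between genotypes, by a test of the interaction, at 9 regions in the higher and 1 in the lower direction under the relative scaling, against 8 and 1590 under the background scaling and 0 and 0 with the replicate number as a block. Of the IgG wt reads in these regions 57.0% (49 of 86) had a score under 0.9, against 37.2% (2694 of 7239) in the other regions, but reads of a region are not independent, and among 10000 draws of as many regions matched on IgG wt reads (median 41.7%) a share of 0.0710 reached this value. A minimum score of 0.9 left 0 calls, but this does not separate low scores from fewer reads, since 20 random thinnings of that library to as many reads left 0 to 6 (median 2). With the minimum score 2 regions had too few reads. The log2 interaction fell from 3.84 ± 0.938 to 0.777 ± 1.83 (SE) on chromosome 2 at 112360007. On chromosome 18 at 44684231 all 4 IgG wt reads had a score under 0.9. There the value went from 8.44 ± 1.76 to 0.704 ± 1058 (SE), which is too uncertain to read as a fall. At the other 6 the interaction kept a share of 0.837 to 0.969 of its size with a similar or larger SE. The median share over the 10 was 0.861, with 0 where reads were too few. At the lower region, on chromosome 9 at 59798837, 0 of the 2 IgG wt reads had a score under 0.9, so such reads cannot make up its fold. Whether low-score reads account for any of the 9 higher calls stays open. Since the IgG wt group is 1 library, no replicate separates its background from the genotype.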

How the results depend on the processing

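Alternatives with a minimum score of 0.9, scaling over regions of both Nrl ko lists, summed wt libraries, a thinned IgG wt library and single libraries left out of the interaction and IgG tests were added after the data were seen. For results that moved, the cause was not tested unless given. Regions higher and lower in Nrl ko numbered 209 and 5140 with TMM over background bins, 229 and 5066 with total reads, 632 and 101 with DESeq2, and 477 and 3288 with TMM over regions of both Nrl ko lists. They numbered 182 and 176 in regions of all 4 lists and 413 and 132 with libraries thinned to the smallest, where fewer regions or reads were tested. In the 50% of regions with the most reads 608 were higher, and with the wt libraries summed 355 were lower. Leaving out single libraries gave 579 to 988 higher and 269 to 570 lower; the lower count was 311 and 269 without wt replicates 1 and 2, and without Nrl ko replicate 2 the counts were 579 and 315. A lone library was assumed to vary like the other groups.

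The interaction gave 26 higher regions with all reads, 22 and 0 (lower) with DESeq2, 0 and 0 with a minimum score of 0.9, 3 and 0 with the IgG wt library thinned to as many reads, and 8 higher and 1590 lower with TMM over background bins. Leaving out single libraries gave 0 to 22 higher and 0 to 1 lower, with 1 and 0 higher without wt replicates 1 and 2, 22 without Crx Nrl ko replicate 1 and 0 without IgG Nrl ko replicate 2. IgG was lower at 23 regions with all reads, 2 with DESeq2, 0 with a minimum score of 0.9 and 1 to 4 with single IgG libraries left out, 1 being without replicate 2. Deviations of libraries with the same replicate number were not correlated across regions (-0.020 and -0.022), but mitochondrial reads made up 0.0918% and 0.0843% of the Nrl ko replicate 2 libraries and 0.0176% and 0.0141% of the replicate 1 libraries, so a pairing by number stays open. A replicate block left 0 higher and 0 lower interaction regions, 3 lower IgG regions and 206 windows with Crx below IgG in wt.

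Windows with Crx above IgG in wt numbered 4647 with all reads, 11763 at 500 bp and 4068 with no filter, and 3418 and 2660 without wt replicates 1 and 2. Those below numbered 1935 with all reads, 65 with DESeq2, 77 with a minimum score of 0.9, 545 at 500 bp, 160 with no filter, and 53 and 49 without wt replicates 1 and 2. In Nrl ko, windows above IgG numbered 723 with all reads, 503 with DESeq2, 3368 at 500 bp and 472 with no filter. They ranged from 277 without Crx replicate 2 to 2963 without IgG replicate 2, with 667 and 651 without Crx and IgG replicate 1. Those below numbered 0 with DESeq2, 37 at 500 bp, 5 with no filter and 0 to 60 without single libraries, 60 being without IgG replicate 1. Between genotypes, higher windows numbered 65 with all reads, 18 with DESeq2, 320 at 500 bp, 28 with no filter and 3 to 60 without single Crx libraries. Lower windows numbered 4412 with all reads, 3615 with DESeq2, 4215 with no filter and 905 to 3689 without single libraries, 905 being without wt replicate 2.

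With 50% of the shorter cluster required, wt replicate 1 was met by Nrl ko replicates 1 and 2 at 44.5% and 30.1%, those met wt replicate 1 at 31.7% and 42.6%, and they met each other at 26.9% and 53.7%. With the 5000 tallest clusters the values were 36.8%, 33.6%, 36.8%, 42.8%, 36.3% and 46.4%, and wt replicate 1 was met by wt replicate 2 at 91.9%.

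Of 1279 values of 100 named regions and windows under alternatives, 1089 kept direction and side of the threshold, 141 lost the call, 30 gained it and 19 changed sign. The region on chromosome 3 at 30644861, not called, was 0.089 with all reads, 0.19 with unmoved reads, 0.29 thinned, -0.29 to 0.28 without single libraries (0.28 without Nrl ko replicate 1) and 0.0068 with a minimum score of 0.9. The region on chromosome 4 at 137886052, not called, was -1.89 with TMM over background bins, -1.79 with total reads, -0.34 in regions of all 4 lists, -0.032 in the 50% with most reads, -0.011 at a fixed 400 bp and -0.83 with TMM over regions of both Nrl ko lists. With background bins and total reads, the tallest Nrl ko regions changed sign on chromosome 6 at 29344226 (-0.88 and -0.79), chromosome 10 at 93761175 (-0.85 and -0.75), chromosome 2 at 93431902 (-0.11 and -0.016) and chromosome 2 at 144345387 (-0.99 and -0.89). With TMM over regions of both Nrl ko lists the 5 tallest wt regions, not called before, were all called lower, and 3 of the 5 tallest Nrl ko regions lost the call, on chromosome 6 at 29344226 (0.179, adjusted p = 0.423), chromosome 10 at 93761175 (0.214, 0.337) and chromosome 2 at 144345387 (0.055, 0.825). In regions of all 4 lists 3 of the tallest wt regions were also called lower, among them that on chromosome 3 at 30644861 (-0.494, edgeR adjusted p = 0.0129). The planned promoter windows, gene lists, location, motifs and GC correction were not run, and 500 bp windows gave no values for single 1 kb windows.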

Other observations

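Among called regions that lay within 10 kb of each other, most changed the same way; such pairs numbered 104, against 1044 higher and 644 lower regions in all. On chromosome 6 from 115878787 to 115889363, 5 regions fell relative to other regions, with log2 changes from -3.97 to -1.09. On chromosome 9 from 59797767 to 59800862 and chromosome 11 from 106634471 to 106638375, 3 regions each fell. On chromosome 1 from 83339434 to 83344979, chromosome 19 from 38206433 to 38208911 and chromosome 6 from 136898002 to 136903175, 3 regions each rose. These groups were picked after their values were seen, and their direction is that of the relative scaling.

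A hypothesis, tested after the pattern was seen, was that called regions within 10 kb change in the same direction. Of 104 neighbouring pairs 89 (85.6%) did, against a mean of 52.8% and a highest value of 72.1% over 10000 permutations of the directions (permutation test, p = 0.0001, the smallest these permutations can give). The share was 90.1% within 5 kb and 80.8% within 50 kb. Signal that spreads from 1 region into its neighbour was not separated from this.

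Clusters found in Nrl ko replicate 1 alone numbered 4348 and had a median of 4 unique reads in that library. Of its reads there 43.5% were duplicates, and 61.2% of these clusters had fewer than 5 unique reads. Reads were counted after the 75 bp move, and these clusters had a median width of 127 bp. Reads that form a narrow cluster can thus be counted outside it, so these values partly reflect the counting rule. Clusters of Nrl ko replicate 2 alone numbered 1308.

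The windows on chromosome 1 at 24619001 and 24620001 had 81 and 57 reads in Crx Nrl ko replicate 2 and 47 and 46 in IgG Nrl ko replicate 2, against 13 and 10 in Crx Nrl ko replicate 1. Mitochondrial reads made up 0.0918% and 0.0843% of unique reads in these replicate 2 libraries and 0.00522% to 0.0176% in the others.

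In shifted bins of chromosome 14, 13 of 53 tested regions were lower in Nrl ko relative to other regions (24.5%) and 6 were higher, against 10.7% lower elsewhere; no test was made that allows for neighbouring regions changing together. The ratio of Nrl ko to wt reads was 0.868 in these bins and 1.05 in other bins of the chromosome, where autosomal bins had a median of 1.03 and an SD of 0.171. On chromosome Y, 8 of 9 tested regions were higher relative to other regions. Among windows, IgG was lower in Nrl ko at 180, of which 29 lay on X, and higher at 1. In the 180 windows 73.4% of the IgG wt reads had a score under 0.9, against 36.4% of its other reads. The higher one, on chromosome 14 at 56179001, had 0 IgG reads in wt and 10 and 35 in Nrl ko, with 38 and 37 Crx reads in wt.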
